A study of Mus musculus with 17 samples.

How the data were processed

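The data are RNA-seq libraries of 17 mouse cell samples. Per the labels' protocols, RNA was taken with Trizol, and samples with a RIN above 7.5 were used. About 250 ng of total RNA went into TruSeq v2 libraries, which were sequenced on HiSeq instruments at separate sites. The submitters' processing notes name CASAVA, TopHat2 2.0.7, Bowtie2 2.0.5 and Cuffdiff 2.1.1, with the builds mm10 and NCBIM37. They give no role for either build, so no coordinates are given. Per the file headers, each deposited sample table holds, for 28670 genes, the estimated counts of fragments assigned by the authors' quantification, a scaled count, the FPKM and a status. Between 97.5% and 98.8% of the estimated counts were whole to within 0.01. FPKM follows the scaled count and gene length. The factor from fragments to scaled count did not follow depth alone. It was 0.4145 in WT ESC 3 (12.7 M fragments) and 0.9999 in Nanog-null iPSC G2 2 (17.7 M). How far this scaling removes a composition difference between libraries was not tested. A deposited table of the series holds the mean FPKM of each of the 7 groups. It lay within 1% of the means of the sample tables for all but 2 genes with an FPKM of at least 1. It was used only for that check.

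Groups and replicate numbers came from the sample titles, and batches from the prefix of the sample codes. The series text speaks of biological replicates, but no label says that they came from separate cultures, so p-values measure the spread between these samples. In comparisons of Nanog-null iPSC, clones G2 and G5 had a term each, so the p-values leave out the spread between the clones. No pair of replicates was a duplicate: their fragments differed beyond sampling noise, with a chi-square per gene of 1.58 to 630. The highest value was that of WT iPSC 1 and 3, of different batches. Pairs within a batch had 1.58 (WT MEF) to 32.4 (WT ESC 3 and 4). These values do not tell libraries of 1 culture from separate cultures. Depth was 17.7 to 43.5 M fragments in AC and 7.80 to 30.1 M in JI. Ribosomal protein genes took 21.1% to 28.6% of assigned fragments in JI samples of WT ESC and WT iPSC, 8.50% to 10.5% in AC samples of these groups and 4.05% in WT MEF. The tests leave out 13 genes with the status FAIL and 6 with HIDATA in some sample, Esrrb and Peg10 among them.

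The groups, comparisons, tests, gene lists, rule for named genes and most alternatives were chosen before the data were examined. Each comparison was tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a trend) on log2(FPKM + 1) of all 17 samples. The fit had a term for each group and for batch and 9 residual degrees of freedom. Genes needed an FPKM of at least 1 in at least 2 samples (15298 genes), and p was adjusted by Benjamini and Hochberg with a threshold of 0.05. A fold change on this scale understates the change of low genes. The main test stayed limma on FPKM. Since the files also gave fragment counts, edgeR 4.0.16 (quasi-likelihood test, TMM scaling, same design, estimated counts rounded to whole numbers) was added as an alternative after seeing the data. So were fits of batch JI alone and fits without the genes called higher in WT MEF than in WT ESC. The other alternatives were a pseudocount of 0.1, no filter, a mean FPKM of at least 5, quantile normalization and no batch term. Further ones were batch AC alone, only the groups compared, the replicate numbers as a block, a fold of at least 2 and leaving out each sample.

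On counts simulated from the real means, depths and dispersions, limma recovered 35.8% of genes changed 1.5-fold, 79.1% of those changed 2-fold and 98.5% of those changed 4-fold in the comparison of Nanog-null ESC with WT ESC (13869 genes). It called 10 unchanged genes. For clone G2 against G5 it recovered 34.3%, 70.1% and 96.9% and called 11. In a simulated G2 against G5 (13886 genes), camera called a list of 20 raised genes and 0 of 18 unchanged lists. All these simulations drew genes independently, without a batch difference, and the changed genes were not among those with few fragments. They therefore do not test correlation between genes or the recovery of low genes.

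Of the 21 lists fixed, 19 were tested with camera (preset correlation of 0.01, adjusted over the 19 lists of a comparison). Lists of cell state held general pluripotency, naive and LIF response, formative and primed epiblast, germline, imprinted and 2-cell stage genes. Lists of other cell types held fibroblast, epithelial, primitive endoderm, trophoblast, primitive streak and mesoderm, neural ectoderm, macrophage and endothelial genes. Lists of responses held ERK, Wnt, p53, stress, and glycolysis and hypoxia genes. Sex-linked genes and the reprogramming factors were read as values. Of 290 members, 282 were matched by symbol and 5 by gene ID, and 3 were not matched. Over the 8 comparisons and the interaction, camera called 69 of the list tests, and 24 with an estimated correlation.

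Nanog, Pou5f1, Sox2, Klf4 and Myc are named in each comparison. Next come the 5 called genes with the largest rise and the 5 with the largest fall, among genes with a mean FPKM of at least 5 in a group compared. The samples of the groups must not overlap, and unnamed gene models are left out. Also named are the 2 called members of each list with the largest change (4 for general pluripotency, naive, fibroblast and primitive endoderm). Where a list's members repeat or a comparison has few calls, fewer are named, and 1 gene that met the rule is not reported here. Others are said to be chosen after their values were seen. The position of a sample between MEF and ESC is its projection, over all genes tested, on the line from the WT MEF mean to the WT ESC mean. Positions were compared by an exact two-sided permutation test, also with WT ESC of only AC or only JI as the ESC end. Figures were drawn with matplotlib 3.10.9, and tables were handled in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6.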

Results

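RNA was sequenced from 17 samples of mouse cells in 7 groups. WT embryonic stem cells (ESC, grown from the inner cell mass of the blastocyst) gave 4 samples. WT induced pluripotent stem cells (iPSC, made from fibroblasts by expressing reprogramming factors) gave 3. WT partially reprogrammed cells (piPSC), Nanog-null ESC, clone G2 and clone G5 of Nanog-null iPSC, and WT embryonic fibroblasts (MEF, passage 2) gave 2 each. The labels' protocols state that Nanog-null MEF were sorted from chimeric embryos and transduced with retroviruses for Oct4, Sox2 and Klf4, with or without c-Myc. Colonies were picked on day 20 onto feeder cells in 2i and LIF. The series title names the question, whether these canonical factors can make iPSC without Nanog, a homeodomain transcription factor of pluripotent cells. The sample codes split the libraries into batch AC (11 libraries, all of the 129/B6 v6.5 strain) and batch JI (6 libraries, all C57/B6), so strain and batch cannot be told apart. WT ESC (2 AC and 2 JI) and WT iPSC (1 AC and 2 JI) lie in both. WT MEF lie only in JI, and the other groups only in AC.

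The files held 7.80 to 43.5 M (mega) assigned fragments per sample. Group ranges were 7.80 to 25.6 M for WT ESC, 14.0 to 30.1 M for WT iPSC, 28.5 to 29.4 M for WT piPSC and 20.4 to 43.5 M for Nanog-null ESC. They were 17.7 to 32.5 M for G2, 23.1 to 24.9 M for G5 and 8.73 to 19.8 M for WT MEF. Between 11737 and 12680 genes had an FPKM (fragments per kilobase of gene per M fragments, here from the scaled count) of at least 1 in a sample. Values are mean FPKM ± SD over the samples of a group, with n as given above. In parentheses after a gene, the mean of the reference group comes first, and the log2 change is on the log2(FPKM + 1) scale ± SE from limma. A gene said to have risen or fallen had a limma adjusted p under 0.05. The largest rises and falls are ranked among called genes with a mean FPKM of at least 5 in a group compared whose samples did not overlap between the groups. List counts are of members called over all genes tested.

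Nanog RNA, the targeted gene, was 568 and 574 FPKM in the AC samples of WT ESC and 295 and 323 in the JI samples. WT iPSC had 762 in the AC sample and 286 and 270 in the JI samples. It was 45.8 and 49.5 in Nanog-null ESC, 27.2 and 27.8 in clone G2 and 40.0 and 43.0 in clone G5. WT piPSC had 3.12 and 2.91, and WT MEF 0.243 and 0.0540. The 6 Nanog-null samples were below every WT ESC and WT iPSC sample and above the piPSC and MEF samples. FPKM of a whole gene does not show whether fragments come from outside the deleted part, so these values do not check the deletion itself.

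**Figure D1:**
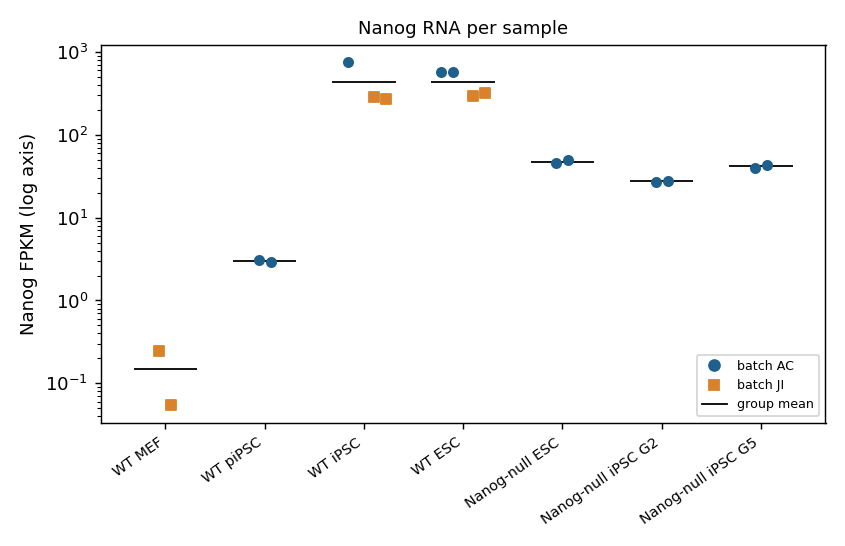
Nanog FPKM (log axis) of each of the 17 samples by group, with circles for batch AC, squares for batch JI and a line at each group mean. The Nanog-null samples lie between 27.2 and 49.5 FPKM, below the 270 to 762 FPKM of WT ESC and WT iPSC and above the piPSC and MEF samples.

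WT MEF and WT ESC are the start and the reference of reprogramming. ESC values here are those of batch JI, which holds the MEF. The largest rises in MEF were those of the matrix genes Thbs1 (9.87 ± 2.09 to 1989 ± 17.6 FPKM, log2 7.60 ± 0.14), Col1a1 (6.21 ± 0.199 to 1239 ± 12.4 FPKM, log2 7.46 ± 0.10) and Tnc (7.13 ± 1.13 to 1308 ± 24.9 FPKM, log2 7.43 ± 0.12). Next came Col5a1 (2.08 ± 0.189 to 251 ± 2.53 FPKM, log2 6.53 ± 0.17) and the interleukin-33 receptor gene Il1rl1 (4.76 ± 1.88 to 875 ± 1.62 FPKM, log2 7.40 ± 0.18). Pluripotency genes were near or at 0 in MEF. Pou5f1, which encodes Oct4, was 1348 ± 335 FPKM in JI ESC and listed at 0 in both MEF samples. Dppa5a, with 13299 ± 5263 in JI ESC, and the Nodal co-receptor gene Tdgf1, with 898 ± 1.36, were likewise listed at 0 in MEF. Nanog (309 ± 19.5 to 0.148 ± 0.133 FPKM, log2 -7.97 ± 0.13) and Sox2 (94.3 ± 13.4 to 0.469 ± 0.186 FPKM, log2 -5.99 ± 0.19) fell as well. The lipid carrier gene Apoc1 (log2 -8.72 ± 0.28) and the chromatin-associated factor gene Utf1 (log2 -7.14 ± 0.19) also fell. Trap1a was 348 ± 99.9 FPKM in JI ESC and listed at 0 in MEF. The factor genes Myc (2.71 ± 0.369 to 125 ± 1.77 FPKM, log2 5.28 ± 0.22) and Klf4 (13.0 ± 1.44 to 35.3 ± 0.282 FPKM, log2 1.41 ± 0.10) were higher in MEF.

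Among general pluripotency genes, 0 of 22 rose and 21 fell (0 and 21 adjusted over the list alone, camera adjusted p = 1.3e-09). Among naive and LIF response genes, 5 of 17 rose and 11 fell (5 and 11 adjusted over the list alone, camera adjusted p = 0.19). The fallen ones included Dppa3 (log2 -7.60 ± 0.39) and the adhesion gene Pecam1 (log2 -4.59 ± 0.19), and Tcl1 was listed at 0 in MEF. Fibroblast genes, among them the collagen genes Col1a2 (log2 6.34 ± 0.14) and Col3a1 (log2 5.94 ± 0.18), were higher. In this list 24 of 25 rose and 0 fell (24 and 0 adjusted over the list alone, camera adjusted p = 1.3e-09). Epithelial genes, such as the adhesion gene Epcam (log2 -7.39 ± 0.31) and the tight junction gene Cldn4 (log2 -6.46 ± 0.34), all moved the other way. In this list 0 of 16 rose and 16 fell (0 and 16 adjusted over the list alone, camera adjusted p = 6e-06, adjusted p = 0.28 with an estimated correlation). Germline genes were lower, as 0 of 15 rose and 15 fell (0 and 15 adjusted over the list alone, camera adjusted p = 6e-06). They included the synaptonemal complex gene Sycp3 (log2 -5.57 ± 0.31), and Hormad1 was listed at 0 in MEF. ERK response genes were higher, as 13 of 15 rose and 0 fell (13 and 0 adjusted over the list alone, camera adjusted p = 6.6e-05, adjusted p = 0.1 with an estimated correlation). Examples were the AP-1 gene Fosl1 (log2 4.45 ± 0.12) and the phosphatase gene Dusp5 (log2 3.86 ± 0.23). Glycolysis and hypoxia genes, such as Bnip3 (log2 -4.99 ± 0.23) and Pdk1 (log2 -4.56 ± 0.33), were lower. In this list 0 of 12 rose and 12 fell (0 and 12 adjusted over the list alone, camera adjusted p = 0.00018, adjusted p = 0.23 with an estimated correlation). Macrophage genes were higher in MEF, where 7 of 8 rose and 0 fell (7 and 0 adjusted over the list alone, camera adjusted p = 0.0011). They included the lysozyme gene Lyz2 (13.1 ± 1.51 to 355 ± 2.93 FPKM, log2 4.56 ± 0.17) and the endotoxin co-receptor gene Cd14 (1.10 ± 0.140 to 55.2 ± 0.0346 FPKM, log2 4.94 ± 0.20). Imprinted genes went both ways, and 14 of 20 rose and 4 fell (14 and 4 adjusted over the list alone, camera adjusted p = 0.049, adjusted p = 0.1 with an estimated correlation). Among them Phlda2 (log2 -4.81 ± 0.15) and Snrpn (log2 -4.55 ± 0.09) were lower.

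In all, limma called 12254 of 15298 genes, 5936 higher and 6318 lower in MEF, and 8047 of them changed at least 2-fold. MEF came only from batch JI, and within JI alone limma called 11472 genes. Klf4 lost its call without the batch term.

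WT iPSC were compared with WT ESC to see how closely fully reprogrammed cells match. The core factors did not pass the test. Nanog was 439 ± 279 against 440.1 ± 152 FPKM (log2 change 0.08 ± 0.11, limma adjusted p = 0.73). Limma gave Pou5f1 a log2 change of -0.03 ± 0.11 (adjusted p = 0.93) and Sox2 one of 0.06 ± 0.15 (adjusted p = 0.87). Klf4 had -0.29 ± 0.08 (limma adjusted p = 0.09) and Myc 0.25 ± 0.18 (adjusted p = 0.46). Small rises were called for the DNA methyltransferase gene Dnmt3a (log2 0.97 ± 0.20), the imprinted adaptor gene Grb10 (log2 0.91 ± 0.16) and the glycosyltransferase gene Galnt6 (log2 0.86 ± 0.13). Others were Plxdc2 (log2 0.83 ± 0.15), the sorbitol dehydrogenase gene Sord (log2 0.81 ± 0.15), the germline gene Tex19.1 (log2 0.60 ± 0.11) and the surface antigen gene Thy1 (log2 0.52 ± 0.10). Among genes without overlap of the samples, the largest falls were those of the adaptor complex gene Ap3b2 (log2 -1.25 ± 0.24), the histone deacetylase gene Hdac7 (log2 -0.87 ± 0.13) and the homeobox gene Vax2 (log2 -0.75 ± 0.13). The protease gene Mmp11 (log2 -0.73 ± 0.15) and the acetyl-CoA synthetase gene Acss1 (log2 -0.67 ± 0.09) followed. The simple epithelial keratin genes Krt8 (177 ± 33.5 to 102 ± 5.41 FPKM, log2 -0.94 ± 0.11) and Krt18 (390.2 ± 116 to 267 ± 5.36 FPKM, log2 -0.88 ± 0.17), given here by their JI means, fell too, with samples that overlapped between the groups. So did the Akt co-activator gene Tcl1 (log2 -0.62 ± 0.12).

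Among the fixed lists, ERK response genes were higher in iPSC by camera, although 0 of 15 rose and 0 fell (9 and 0 adjusted over the list alone, camera adjusted p = 7.7e-05, adjusted p = 0.19 with an estimated correlation). General pluripotency genes were also higher by camera, with single genes called over the list alone, as 0 of 22 rose and 0 fell (8 and 1 adjusted over the list alone, camera adjusted p = 0.0019, adjusted p = 0.19 with an estimated correlation). In the formative and primed epiblast list 1 of 14 rose and 0 fell (7 and 0 adjusted over the list alone, camera adjusted p = 0.0019, adjusted p = 0.37 with an estimated correlation). In the 2-cell stage list 0 of 9 rose and 0 fell (6 and 0 adjusted over the list alone, camera adjusted p = 0.00075, adjusted p = 0.41 with an estimated correlation). Its member Zscan4c, chosen after its values were seen, was 114 FPKM in the AC iPSC sample and 15.3 in AC ESC. In JI it was 0.275 in iPSC and 0.406 in ESC. Zscan4d and Zscan4f were likewise higher in iPSC only in AC. Epithelial genes were lower, and 1 of 16 rose and 2 fell (1 and 3 adjusted over the list alone, camera adjusted p = 0.0019, adjusted p = 0.41 with an estimated correlation). Fibroblast, primitive endoderm and p53 response genes were higher by camera. In the fibroblast list 1 of 25 rose and 0 fell (6 and 0 adjusted over the list alone, camera adjusted p = 0.0011, adjusted p = 0.23 with an estimated correlation). For primitive endoderm genes 0 of 19 rose and 0 fell (4 and 0 adjusted over the list alone, camera adjusted p = 0.0072, adjusted p = 0.21 with an estimated correlation). For p53 response genes 0 of 12 rose and 0 fell (5 and 1 adjusted over the list alone, camera adjusted p = 0.0095, adjusted p = 0.41 with an estimated correlation). Trophoblast genes were lower by camera, and 0 of 10 rose and 0 fell (0 and 4 adjusted over the list alone, camera adjusted p = 0.0072, adjusted p = 0.19 with an estimated correlation). Most members of these lists passed no gene-level test over all genes.

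Limma called 156 genes, 98 higher (62.8%) and 58 lower, and 5 of them changed at least 2-fold. By edgeR on the rounded fragments 1319 were called, of which 76.2% were higher. The limma count rested on single libraries. It was 28 without WT ESC 1, 11 without WT ESC 2, 2675 without WT ESC 3, 1809 without WT ESC 4 and 84 without WT iPSC 2. Of the 15 named genes called, 10 lost the call without WT ESC 1, 13 without WT ESC 2, 9 without WT iPSC 1, 5 without WT iPSC 2 and 3 without WT iPSC 3. Acss1 and Krt8 kept it in each of these. Klf4 was called by limma without WT ESC 3 (adjusted p = 0.028) and Pou5f1 without WT ESC 4 (adjusted p = 0.036). Within AC, with 1 iPSC sample, limma called 6191 genes. Among them were Nanog (log2 change 0.42, limma adjusted p = 0.0023), Myc (0.81, adjusted p = 0.016) and Pou5f1 (-0.25, adjusted p = 0.037). Within JI it called 0, with 945 at an unadjusted p under 0.05 and 3 called by edgeR. The iPSC minus ESC differences of the batches had a correlation across genes of -0.0105, and 50.3% of all genes tested had the same sign in both. Without the batch term limma called 0 genes (910 at an unadjusted p under 0.05, 0 by edgeR), all 15 named calls were lost and the log2 change of Krt18 turned to 0.11 (limma adjusted p = 0.99). With only these groups in the fit it called 0 as well (1318 at an unadjusted p under 0.05, 8 by edgeR), and again all 15 were lost. A lone remaining sample is assumed to vary like the other groups in this and the later fits.

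WT piPSC, which stopped before full reprogramming, were set against WT iPSC, whose values here are those of the AC sample. The largest rises were those of the amino acid transporter gene Slc38a5 (2.60 to 1941 ± 14.8 FPKM, log2 8.93 ± 0.49), Myc (6.85 to 1372 ± 190.3 FPKM, log2 7.82 ± 0.25) and Nccrp1 (0.837 to 471 ± 105 FPKM, log2 7.66 ± 0.24). The galectin gene Lgals7 (1.06 to 336 ± 38.3 FPKM, log2 7.11 ± 0.27) and the lymphocyte antigen gene Ly6c1 (1.38 to 351 ± 9.47 FPKM, log2 6.91 ± 0.23) came next. Klf4 (57.6 to 2806 ± 366 FPKM, log2 5.65 ± 0.11) and Pou5f1 (639.5 to 7139 ± 232 FPKM, log2 3.33 ± 0.15) were also above iPSC. These gene-level values do not separate endogenous RNA from RNA of the retroviral copies. In contrast, Nanog (762 to 3.01 ± 0.146 FPKM, log2 -7.34 ± 0.14) and Sox2 (156 to 40.1 ± 16.2 FPKM, log2 -1.94 ± 0.21) were lower. Besides Nanog, the largest falls were those of Dppa5a (4384 to 18.5 ± 0.383 FPKM, log2 -8.10 ± 0.25), the osteopontin gene Spp1 (log2 -7.70 ± 0.14), the uridine phosphorylase gene Upp1 (log2 -6.77 ± 0.13) and Calcoco2 (log2 -6.79 ± 0.14).

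Among general pluripotency genes, which were lower as a list, 1 of 22 rose and 19 fell (1 and 19 adjusted over the list alone, camera adjusted p = 6.6e-08). Pou5f1 was the member that rose. Those that fell included Dppa2 (log2 -6.38 ± 0.29), Utf1 (log2 -5.59 ± 0.21) and the Nodal antagonist gene Lefty2 (log2 -5.75 ± 0.25). Naive and LIF response genes were lower too, as 4 of 17 rose and 13 fell (4 and 13 adjusted over the list alone, camera adjusted p = 0.012, adjusted p = 0.43 with an estimated correlation). The transcription factor genes Klf2 (log2 -5.67 ± 0.17) and Tbx3 (log2 -5.40 ± 0.26) fell, though Klf4 rose. Germline genes, such as Dazl (log2 -5.18 ± 0.27) and Tex19.1 (log2 -5.12 ± 0.15), were lower, and 1 of 15 rose and 14 fell (1 and 14 adjusted over the list alone, camera adjusted p = 6.8e-06). For 2-cell stage genes, 0 of 9 rose and 9 fell (0 and 9 adjusted over the list alone, camera adjusted p = 0.0033, adjusted p = 0.54 with an estimated correlation). They included Zscan4f (log2 -5.81 ± 0.57) and Zscan4c (log2 -5.47 ± 0.57), whose near-identical copies share reads and which were high in iPSC only in the AC sample. ERK response genes were higher, where 9 of 15 rose and 1 fell (9 and 1 adjusted over the list alone, camera adjusted p = 0.022, adjusted p = 0.43 with an estimated correlation). They were led by Dusp4 (log2 5.15 ± 0.17) and Spry4 (log2 3.78 ± 0.12). Epithelial genes, such as Cldn4 (log2 -4.30 ± 0.38) and the E-cadherin gene Cdh1 (log2 -3.27 ± 0.26), were lower. In this list 2 of 16 rose and 11 fell (2 and 13 adjusted over the list alone, camera adjusted p = 0.02, adjusted p = 0.54 with an estimated correlation). Fibroblast genes split, as 8 of 25 rose and 13 fell (8 and 15 adjusted over the list alone, camera adjusted p = 0.059). The hyaluronan receptor gene Cd44 (3.23 to 108 ± 0.252 FPKM, log2 4.65 ± 0.10) rose. Col1a1 (63.0 to 0.342 ± 0.0315 FPKM, log2 -5.51 ± 0.11), Col1a2 (log2 -5.14 ± 0.15) and Col3a1 (log2 -4.88 ± 0.20) fell. Imprinted genes Meg3 (log2 -5.17 ± 0.31) and Grb10 (log2 -4.97 ± 0.22) fell, and in their list 2 of 20 rose and 10 fell (2 and 10 adjusted over the list alone, camera adjusted p = 0.058).

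Limma called 9896 genes, 4662 higher and 5234 lower in piPSC, and 11247 within AC alone. Zscan4f and Zscan4c lost their call without the batch term.

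Nanog-null ESC were compared with WT ESC, as lines labelled Nanog -/- and WT that were not reprogrammed. The labels give passage 6 for Nanog-null ESC and passages 10 to 15 for WT ESC. The protocols describe feeder cells with 2i and LIF for the Nanog-null lines, and the medium of WT ESC is not given in the sources used here. Line and passage therefore differ together with genotype. Values of WT ESC are those of batch AC, which holds all Nanog-null samples. Nanog (571 ± 3.93 to 47.7 ± 2.64 FPKM, log2 -3.67 ± 0.13) fell. The FGF ligand gene Fgf4 (81.0 ± 2.64 to 5.60 ± 0.476 FPKM, log2 -3.60 ± 0.11) and the germline regulator gene Prdm14 (22.9 ± 0.803 to 3.28 ± 0.0186 FPKM, log2 -2.59 ± 0.14) fell too. Sox2 (142 ± 0.956 to 51.9 ± 0.828 FPKM, log2 -1.46 ± 0.19) and Klf4 (65.2 ± 0.218 to 29.1 ± 1.76 FPKM, log2 -1.18 ± 0.10) were lower by less. Pou5f1 was 591 ± 1.91 against 758 ± 2.24 FPKM (log2 change -0.29 ± 0.14, limma adjusted p = 0.099). It passed the threshold without WT ESC 4 (log2 change -0.34, limma adjusted p = 0.00026) and within AC (log2 change -0.36, adjusted p = 0.0011). Extraembryonic endoderm genes rose, led by the basement membrane collagen genes Col4a1 (4.68 ± 0.440 to 204 ± 0.689 FPKM, log2 5.00 ± 0.19) and Col4a2 (3.73 ± 0.236 to 127 ± 0.513 FPKM, log2 4.65 ± 0.15). The laminin gene Lama1 (5.47 ± 0.114 to 86.4 ± 1.80 FPKM, log2 4.04 ± 0.26) and the transcription factor gene Gata6 (0.308 ± 0.0714 to 18.5 ± 0.359 FPKM, log2 3.92 ± 0.11) followed. Myc (3.52 ± 0.971 to 18.7 ± 2.56 FPKM, log2 1.95 ± 0.22) rose as well.

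Other large rises were those of the ATP-gated channel gene P2rx7 (2.07 ± 0.329 to 113 ± 0.128 FPKM, log2 5.19 ± 0.13), the RNA export family gene Nxf7 (0.632 ± 0.251 to 63.4 ± 0.329 FPKM, log2 5.32 ± 0.13) and Dppa1 (0.155 ± 0.0935 to 35 ± 0.230 FPKM, log2 5.00 ± 0.12). AC154650.1 (564 ± 479 FPKM, listed at 0 in WT ESC) and AL928557.1 (35.5 ± 0.101, likewise 0) met the same rule but rested on 1 or 2 fragments a sample. They were not called by edgeR (adjusted p = 0.16 and 0.1). Besides Nanog and Fgf4, the largest falls were those of the interferon-induced membrane protein gene Ifitm1 (227 ± 5.42 to 7.50 ± 0.0856 FPKM, log2 -4.32 ± 0.45) and the purine salvage gene Hprt (123 ± 4.92 to 6.94 ± 0.0414 FPKM, log2 -3.86 ± 0.15). The meiotic kinase gene Aurkc (99.3 ± 2.16 to 6.52 ± 0.344 FPKM, log2 -3.72 ± 0.15) fell likewise.

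Primitive endoderm genes rose together, as 18 of 19 rose and 0 fell (19 and 0 adjusted over the list alone, camera adjusted p = 1.6e-15). Fibroblast genes, which would also mark the feeder cells these lines grow on, were higher too. In this list 23 of 25 rose and 0 fell (23 and 0 adjusted over the list alone, camera adjusted p = 2.3e-12). Examples were the smooth muscle actin gene Acta2 (log2 2.99 ± 0.17), the PDGF receptor gene Pdgfra (log2 2.79 ± 0.13) and Col5a2 (log2 2.65 ± 0.16). Among trophoblast genes, 8 of 10 rose and 1 fell (8 and 1 adjusted over the list alone, camera adjusted p = 0.00025). Plac1 (0.0954 ± 0.135 to 22.8 ± 3.58 FPKM, log2 4.24 ± 0.22) and Gata2 (0.755 ± 0.0840 to 29.9 ± 2.02 FPKM, log2 4.16 ± 0.12) were among the risen. Among imprinted genes, 13 of 20 rose and 1 fell (13 and 2 adjusted over the list alone, camera adjusted p = 0.0016). These included H19 (65.3 ± 2.64 to 1323 ± 43.4 FPKM, log2 4.36 ± 0.19) and Phlda2 (11.1 ± 0.369 to 194 ± 32.8 FPKM, log2 3.99 ± 0.15). General pluripotency genes moved both ways, and 2 of 22 rose and 11 fell (2 and 11 adjusted over the list alone, camera adjusted p = 0.0085, adjusted p = 0.17 with an estimated correlation). Fgf4 and the Nodal antagonist gene Lefty2 (log2 -2.78 ± 0.23) fell. The methyltransferase cofactor gene Dnmt3l (2.87 ± 0.480 to 130.5 ± 0.221 FPKM, log2 4.64 ± 0.40) and the RNA-binding protein gene Lin28a (4.47 ± 0.302 to 31.0 ± 2.08 FPKM, log2 2.29 ± 0.23) rose. Naive and LIF response genes also split, as 4 of 17 rose and 9 fell (4 and 9 adjusted over the list alone, camera adjusted p = 0.047, adjusted p = 0.33 with an estimated correlation). Tcl1 (log2 -1.73 ± 0.14) and Prdm14 were lower and the LIF feedback gene Socs3 (log2 1.88 ± 0.15) higher.

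ERK response genes, such as Etv4 (log2 2.28 ± 0.35) and Phlda1 (log2 1.84 ± 0.14), were higher. In this list 11 of 15 rose and 0 fell (11 and 0 adjusted over the list alone, camera adjusted p = 0.0016, adjusted p = 0.17 with an estimated correlation). Also higher were p53 response genes, where 9 of 12 rose and 0 fell (9 and 0 adjusted over the list alone, camera adjusted p = 0.0076, adjusted p = 0.33 with an estimated correlation). They included the cell cycle inhibitor gene Cdkn1a (log2 1.10 ± 0.13) and Perp (log2 1.59 ± 0.08). Germline genes such as Dazl (log2 -3.20 ± 0.24) and the helicase gene Ddx4 (log2 -1.79 ± 0.18) were lower, and 0 of 15 rose and 8 fell (0 and 8 adjusted over the list alone, camera adjusted p = 0.0076). Glycolysis and hypoxia genes were lower as well, as 1 of 12 rose and 9 fell (2 and 9 adjusted over the list alone, camera adjusted p = 0.009, adjusted p = 0.33 with an estimated correlation). The phosphofructokinase gene Pfkp (log2 -2.32 ± 0.12) and the lactate dehydrogenase gene Ldha (log2 -1.77 ± 0.21) were examples. Single members of lists with no camera call also moved. The epithelial keratin genes Krt8 (6.52 ± 0.0955 to 221 ± 10.9 FPKM, log2 4.97 ± 0.14) and Krt18 (6.85 ± 0.0135 to 195 ± 11.4 FPKM, log2 4.83 ± 0.21) rose, and of their list 6 of 16 rose and 2 fell (6 and 2 adjusted over the list alone, camera adjusted p = 0.074). The DNA methyltransferase gene Dnmt3b (log2 3.46 ± 0.34) and Wnt8a (log2 1.87 ± 0.17) belong to the formative and primed epiblast list, where 5 of 14 rose and 3 fell (5 and 3 adjusted over the list alone, camera adjusted p = 0.82). The Wnt antagonist gene Dkk1 (log2 3.34 ± 0.14) is in the Wnt response list, where 8 of 12 rose and 2 fell (8 and 2 adjusted over the list alone, camera adjusted p = 0.11). Further lists were not called by camera. For macrophage genes 2 of 8 rose and 0 fell (2 and 0 adjusted over the list alone, camera adjusted p = 0.19). For endothelial genes 3 of 7 rose and 1 fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.19). For stress genes 5 of 12 rose and 3 fell (5 and 3 adjusted over the list alone, camera adjusted p = 0.19). For 2-cell stage genes in this comparison 0 of 9 rose and 1 fell (0 and 0 adjusted over the list alone, camera adjusted p = 0.19). For primitive streak and mesoderm genes 1 of 5 rose and 1 fell (1 and 1 adjusted over the list alone, camera adjusted p = 0.84). For neural ectoderm genes 3 of 8 rose and 3 fell (4 and 3 adjusted over the list alone, camera adjusted p = 0.84), with a positive median change (0.34) and a negative mean (-0.18).

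In all, limma called 8228 genes, 4185 higher and 4043 lower in Nanog-null ESC, and 2391 of them changed at least 2-fold. Within AC alone it called 10537. Without the batch term the count was 4888, and 11 of the 43 named genes called lost their call. These were Krt8, Krt18, H19, Acta2, Dnmt3l, Lin28a, Lefty2, Klf4, Etv4, Dazl and Perp. Krt18 differed between the batches in WT ESC (6.85 FPKM in AC and 390.2 in JI). Leaving out the genes called higher in MEF, 4898 of 9362 genes were called and 32.6% of them were higher.

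Nanog-null iPSC, as the mean of clones G2 and G5, were compared with WT iPSC, as reprogrammed cells of the 2 genotypes. Here and in later comparisons of Nanog-null iPSC, p-values leave out the spread between the clones, which differed in 820 genes by limma. The clones and the AC sample of WT iPSC were at passage 6, and the JI samples of WT iPSC at passages 10 to 15. Values of WT iPSC are those of its AC sample, 1 library that stood apart from AC samples of WT ESC in some genes (see other observations). Nanog (762 to 34.5 ± 8.18 FPKM, log2 -4.23 ± 0.13) and Fgf4 (75.9 to 8.62 ± 1.17 FPKM, log2 -3.09 ± 0.11) fell. Sox2 (156 to 40.4 ± 1.54 FPKM, log2 -1.87 ± 0.18) and Klf4 (57.6 to 23.2 ± 3.02 FPKM, log2 -1.21 ± 0.10) were lower as well. Pou5f1 was 566 ± 46.2 FPKM against 639.5 in that sample (log2 change -0.33 ± 0.13, limma adjusted p = 0.055). It passed the threshold without WT iPSC 1 (log2 change -0.54, limma adjusted p = 0.021) and without the batch term (log2 change -0.96, adjusted p = 0.024). Myc (6.85 to 8.84 ± 1.71 FPKM, log2 0.69 ± 0.22) rose. The largest rises were those of the keratin genes Krt8 (2.30 to 562 ± 234 FPKM, log2 7.15 ± 0.14) and Krt18 (1.90 to 535 ± 220.4 FPKM, log2 7.06 ± 0.20) and the gap junction gene Gjb2 (0.212 to 68.3 ± 14.6 FPKM, log2 5.81 ± 0.12). The X-linked homeobox genes Rhox6 (1.44 to 148 ± 51.4 FPKM, log2 5.79 ± 0.20) and Rhox9 (1.18 to 127 ± 45.4 FPKM, log2 5.70 ± 0.20), a pair of paralogs that share reads, followed. Besides Nanog, the largest falls were those of the testis cytochrome gene Cyct (80.1 to 5.28 ± 2.33 FPKM, log2 -3.88 ± 0.15) and Hprt (106 to 8.69 ± 3.18 FPKM, log2 -3.73 ± 0.14). The germ cell RNA-binding protein gene Dazl (58.6 to 2.46 ± 0.415 FPKM, log2 -3.60 ± 0.24) and the piRNA pathway gene Tdrd12 (26.7 to 2.63 ± 0.490 FPKM, log2 -3.52 ± 0.26) came next.

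Among primitive endoderm genes, 18 of 19 rose and 0 fell (18 and 0 adjusted over the list alone, camera adjusted p = 1.8e-10). At the top were Gata6 (0.240 to 17.5 ± 2.98 FPKM, log2 3.83 ± 0.11), Col4a1 (log2 3.59 ± 0.19), Col4a2 (log2 3.39 ± 0.15) and the forkhead gene Foxq1 (log2 3.42 ± 0.12). Fibroblast genes, including Pdgfra (log2 2.66 ± 0.13) and the matrix proteoglycan gene Dcn (log2 2.63 ± 0.38), were higher, and 22 of 25 rose and 0 fell (23 and 0 adjusted over the list alone, camera adjusted p = 3.9e-10). Trophoblast genes were higher, as 8 of 10 rose and 1 fell (8 and 1 adjusted over the list alone, camera adjusted p = 0.00036). Gata2 (0.349 to 30.4 ± 3.57 FPKM, log2 4.48 ± 0.12) and the keratin gene Krt7 (0.193 to 72.5 ± 33.0 FPKM, log2 5.30 ± 0.28) were among them. Epithelial genes were higher as well, where 13 of 16 rose and 0 fell (13 and 1 adjusted over the list alone, camera adjusted p = 0.00037, adjusted p = 0.47 with an estimated correlation). In the imprinted list 10 of 20 rose and 3 fell (10 and 3 adjusted over the list alone, camera adjusted p = 0.0056). It included H19 (71.2 to 2019 ± 174 FPKM, log2 4.72 ± 0.18) and the growth factor gene Igf2 (22.5 to 174 ± 22.3 FPKM, log2 3.36 ± 0.22). General pluripotency genes were lower, as 1 of 22 rose and 17 fell (1 and 18 adjusted over the list alone, camera adjusted p = 7.3e-05). Fgf4, Sox2, the Ras family gene Eras (log2 -1.65 ± 0.20) and Lefty1 (log2 -1.65 ± 0.11) were among those that fell. Germline genes, for example Hormad1 (log2 -2.63 ± 0.20), were lower, and 2 of 15 rose and 9 fell (2 and 9 adjusted over the list alone, camera adjusted p = 0.025, adjusted p = 0.082 with an estimated correlation). Glycolysis and hypoxia genes were also lower as a list, and 1 of 12 rose and 8 fell (1 and 8 adjusted over the list alone, camera adjusted p = 0.023, adjusted p = 0.47 with an estimated correlation). Pfkp (log2 -2.13 ± 0.12) fell and the glucose transporter gene Slc2a1 (log2 1.88 ± 0.25) rose. Naive and LIF response genes were not called as a list, though Prdm14 (log2 -2.26 ± 0.13) and Pecam1 (log2 -2.12 ± 0.18) fell. In this list 3 of 17 rose and 8 fell (3 and 8 adjusted over the list alone, camera adjusted p = 0.066).

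Limma called 8778 genes, 4389 higher and 4389 lower, and 2726 of them changed at least 2-fold. Within AC alone, where WT iPSC had 1 sample, it called 10253. Without the batch term Krt18, H19, Igf2, Prdm14, Klf4 and Slc2a1 lost their call, and the log2 change of Klf4 turned to 0.33 (limma adjusted p = 0.70). With only these groups in the fit Myc lost its call. Leaving out the genes called higher in MEF, 5332 of 9362 genes were called and 34.2% of them were higher. The call against MEF shares the batch term with this comparison.

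**Figure D2:**
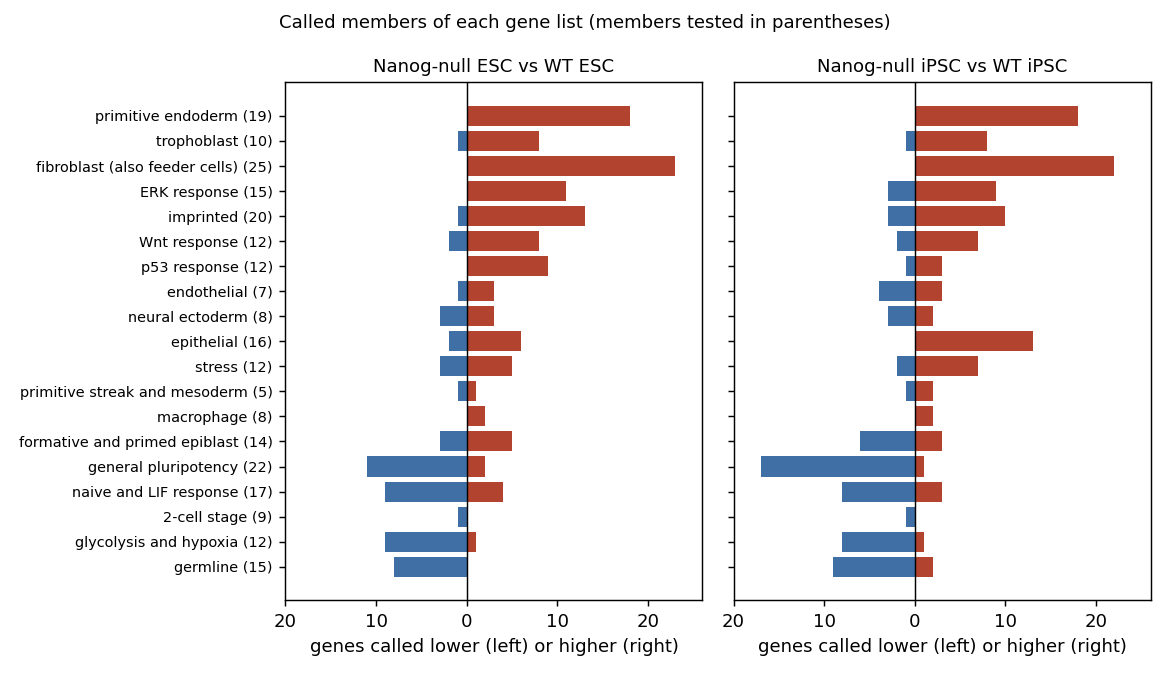
Number of called members of each fixed gene list in Nanog-null ESC against WT ESC and in Nanog-null iPSC against WT iPSC, with members called higher to the right and members called lower to the left, and members tested in parentheses. Primitive endoderm has 18 of 19 members called higher in both panels, and general pluripotency has 11 and 17 members called lower.

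The comparisons of the Nanog-null lines with their WT counterparts overlapped. In both, 3341 genes were higher, where independent lists would share 1201, and 3165 were lower, against 1160. Opposite directions were called for 78 genes. The log2 changes had a correlation of 0.850 across genes and a covariance of 0.587. The comparisons use different WT samples but share the batch term and the estimate of spread. In 20 simulations of unchanged groups in the same design, at most 0 calls were shared, and the correlation was 0.210 and the covariance 0.00787. As no group was changed there, a shared count near 0 was set in advance. The simulations speak only to what the shared batch term adds to the correlation. Within AC alone, where the comparisons share no library and no batch term, 7088 genes were called in the same direction in both, against 6506 in the fit of all samples. Genes are not independent replicates.

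**Figure D3:**
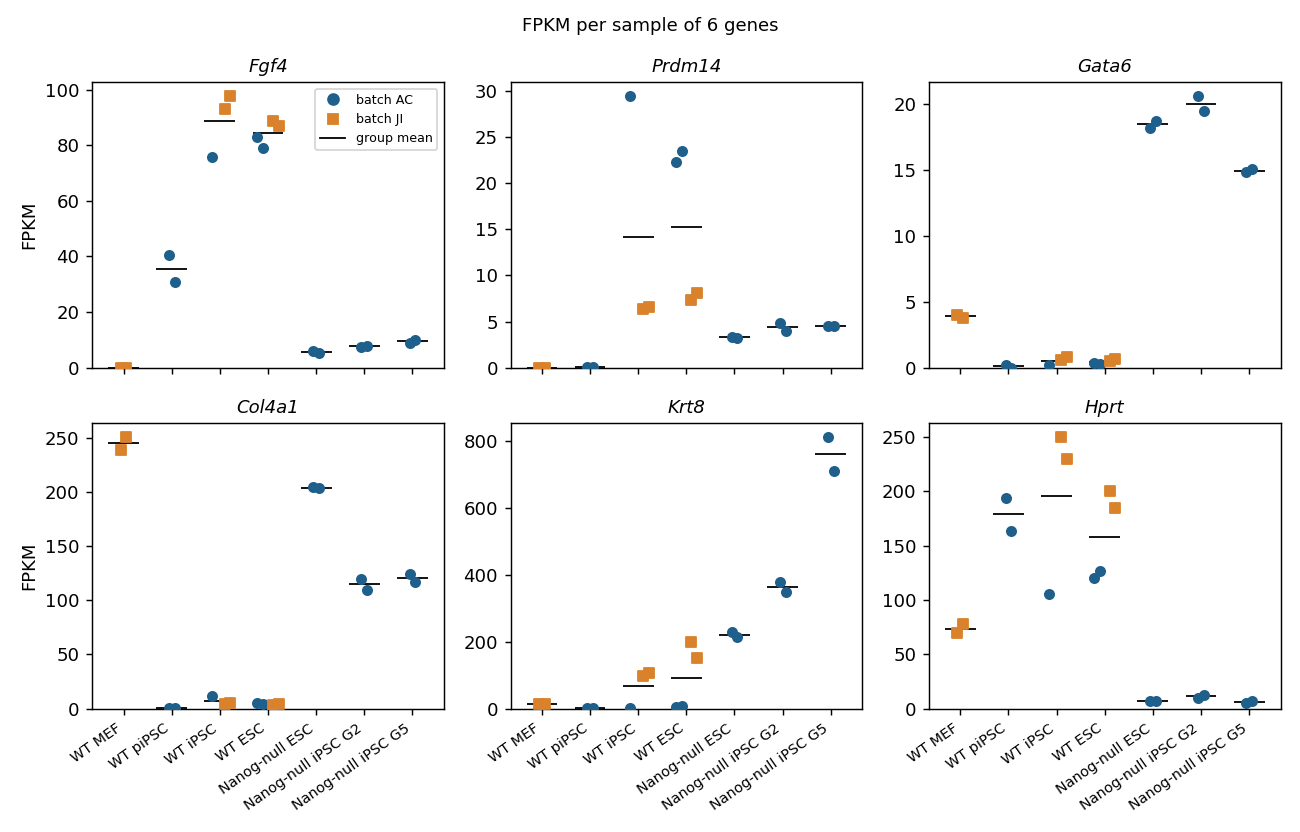
FPKM of 6 genes in each sample by group, with circles for batch AC, squares for batch JI and a line at each group mean. Fgf4, Prdm14 and Hprt are lower and Gata6 and Krt8 higher in the Nanog-null groups than in AC samples of WT ESC and WT iPSC, and Col4a1 in Nanog-null ESC reaches 204 FPKM against 245 in MEF.

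On a scale from the mean of WT MEF (0) to the mean of WT ESC (1) over all genes tested, WT iPSC lay at 0.996 ± 0.0971 (SD, n = 3) and Nanog-null iPSC at 0.701 ± 0.0351 (SD, n = 4). The difference of -0.295 had an exact two-sided permutation p of 0.0286, the smallest that 35 splits allow. These splits exchange samples between batches, although all Nanog-null iPSC are of AC and 2 of the 3 WT iPSC of JI. Exchanged only within batch, the samples make 5 splits, whose smallest exact p, 0.2, was that of the difference. With only the AC samples of WT ESC as the ESC end, the batch of all Nanog-null iPSC, the difference was -0.191, and with only the JI samples it was -0.338 (exact permutation p = 0.0286 in both). Within AC the WT iPSC sample lay at 0.884 and WT ESC at 0.961 ± 0.00642 (SD, n = 2), while the JI means were 1.05 for WT iPSC and 1.04 for WT ESC. Nanog-null ESC lay at 0.706 ± 0.000870 (SD, n = 2), clone G2 at 0.672, clone G5 at 0.731 and WT piPSC at 0.628 ± 0.00117 (SD, n = 2). Leaving out any 1 sample left a difference of -0.351 to -0.266 with an exact p of 0.0667 or 0.1, the smallest possible with 6 samples.

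**Figure D4:**
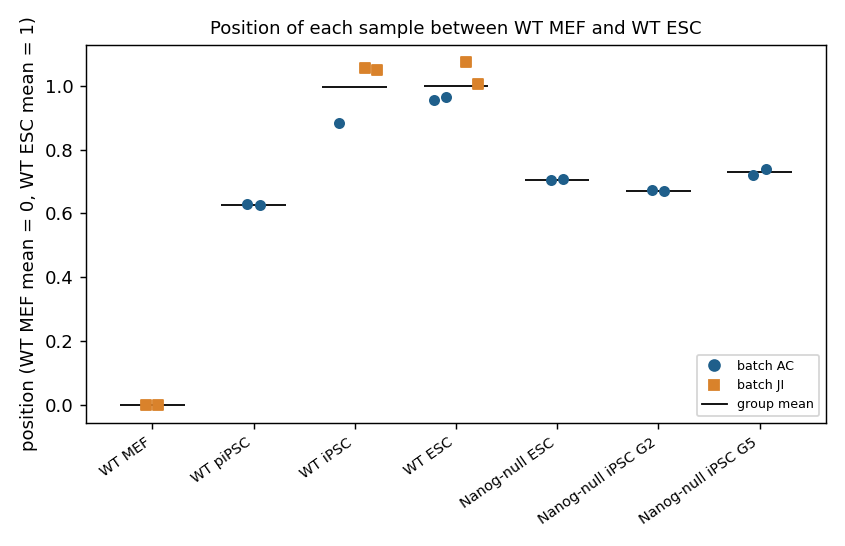
Position of each sample on the axis from the WT MEF mean (0) to the WT ESC mean (1), with circles for batch AC, squares for batch JI and a line at each group mean. The 4 Nanog-null iPSC samples lie between 0.669 and 0.740, below the 3 WT iPSC samples at 0.884 to 1.05.

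Nanog-null iPSC were next compared with Nanog-null ESC, which carry the same genotype label but were not reprogrammed. All are of batch AC. Primitive endoderm genes were lower in the iPSC, as 0 of 19 rose and 11 fell (0 and 11 adjusted over the list alone, camera adjusted p = 2.6e-08). They included the thyroxine carrier gene Ttr (2.71 ± 0.0656 to 0.200 ± 0.0277 FPKM, log2 -1.63 ± 0.07) and Lama1 (86.4 ± 1.80 to 41.4 ± 2.12 FPKM, log2 -1.04 ± 0.24). The endocytic receptor gene Lrp2 (6.91 ± 0.261 to 2.91 ± 0.103 FPKM, log2 -1.02 ± 0.16) and Col4a2 (127 ± 0.513 to 71.4 ± 3.56 FPKM, log2 -0.83 ± 0.14) were others. Among the largest rises were those of the serpin gene Serpinb9e (4.97 ± 0.383 to 29.3 ± 8.17 FPKM, log2 2.31 ± 0.13) and the secretin gene Sct (15.3 ± 1.98 to 75.8 ± 26.8 FPKM, log2 2.18 ± 0.17). The iron exporter gene Slc40a1 (5.95 ± 0.442 to 27.3 ± 1.27 FPKM, log2 2.03 ± 0.17) and Fam78b (2.08 ± 0.546 to 10.3 ± 1.92 FPKM, log2 1.88 ± 0.16) also rose. The Y-linked genes Ddx3y (22.8 ± 0.254 to 1.57 ± 0.507 FPKM, log2 -3.23 ± 0.37), Ube1y1 (7.99 ± 0.271 to 0.0165 ± 0.00737 FPKM, log2 -3.14 ± 0.28) and Eif2s3y (24.7 ± 0.458 to 3.19 ± 1.10 FPKM, log2 -2.66 ± 0.67) fell most. The imprinted gene Phlda2 (194 ± 32.8 to 32.7 ± 3.87 FPKM, log2 -2.53 ± 0.14) followed. AL928557.1 met the same rule but rested on 1 or 2 fragments and was not called by edgeR (adjusted p = 0.2). Nanog (47.7 ± 2.64 to 34.5 ± 8.18 FPKM, log2 -0.48 ± 0.12), Klf4 (29.1 ± 1.76 to 23.2 ± 3.02 FPKM, log2 -0.33 ± 0.09) and Myc (18.7 ± 2.56 to 8.84 ± 1.71 FPKM, log2 -1.01 ± 0.20) were lower in the iPSC. Pou5f1 (log2 change -0.07 ± 0.13, limma adjusted p = 0.85) and Sox2 (log2 change -0.35 ± 0.17, adjusted p = 0.23) did not pass. In a limma fit of these groups alone Sox2 did (adjusted p = 0.0013).

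Epithelial genes, for example the claudin gene Cldn3 (log2 1.52 ± 0.25), were higher as a list, and 5 of 16 rose and 0 fell (7 and 1 adjusted over the list alone, camera adjusted p = 0.0001, adjusted p = 0.56 with an estimated correlation). Among 2-cell stage genes, whose copies share reads, 1 of 9 rose and 0 fell (2 and 0 adjusted over the list alone, camera adjusted p = 0.0063, adjusted p = 0.56 with an estimated correlation). General pluripotency genes were not called as a list, and 2 of 22 rose and 4 fell (4 and 6 adjusted over the list alone, camera adjusted p = 0.1). In it Dnmt3l (log2 -2.08 ± 0.37) and Lin28a (log2 -1.47 ± 0.21) were lower and Lefty2 (log2 0.98 ± 0.21) higher. Limma called 1654 genes, 947 higher and 707 lower, and 247 of them changed at least 2-fold. The count was 537 without Nanog-null ESC 1, 556 without Nanog-null ESC 2, 1082 and 1090 without G2 1 and G2 2 and 1054 without G5 1. Of the 20 named genes called, 7 (AL928557.1, Eif2s3y, Klf4, Lama1, Lefty2, Myc and Nanog) lost the call without Nanog-null ESC 1. Without Nanog-null ESC 2, 6 did so. Leaving out any of G2 1, G2 2 and G5 1 cost 3 calls, and leaving out G5 2 cost 2. In AC alone 4545 genes were called. The count without the batch term was 274, and 14 of the 20 named calls were lost.

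The iPSC minus ESC difference was then compared between Nanog-null and WT lines with an interaction term. It was lower in the Nanog-null lines for Dnmt3l (log2 -3.07 ± 0.49), Lin28a (log2 -2.19 ± 0.29) and Ttr (log2 -1.65 ± 0.10). The same was true of Col4a1 (log2 -1.41 ± 0.24), Col4a2 (log2 -1.25 ± 0.19), Myc (log2 -1.26 ± 0.27) and Nanog (log2 -0.56 ± 0.16). For Krt18 (log2 2.24 ± 0.25) it was higher. Klf4 (log2 -0.04 ± 0.12), Pou5f1 (log2 -0.04 ± 0.17) and Sox2 (log2 -0.41 ± 0.23) did not pass (limma adjusted p = 0.9, 0.92 and 0.28). In the lists, rose and fell refer here to the sign of the interaction. The difference was lower for primitive endoderm genes, as 0 of 19 rose and 9 fell (0 and 12 adjusted over the list alone, camera adjusted p = 1.1e-08). It was higher for epithelial genes, as 7 of 16 rose and 0 fell (11 and 1 adjusted over the list alone, camera adjusted p = 3e-05, adjusted p = 0.41 with an estimated correlation). Limma called 1686 genes (52.5% positive) and edgeR 2549 (37.6% positive). The limma count was 593 and 641 without Nanog-null ESC 1 and 2, and 1064, 1096 and 1039 without G2 1, G2 2 and G5 1. Without WT ESC 3 and WT ESC 4 it was 3151 and 3290. In AC alone it was 6674. Without the batch term it was 158, and all 8 named calls were lost. Nanog lost its call without any of Nanog-null ESC 1 and 2, G2 1 and 2, G5 1 and 2, WT ESC 1 and 2 and WT iPSC 1, and Myc without Nanog-null ESC 1.

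Nanog-null iPSC were also set against WT piPSC, to place them relative to cells that stopped partway. Nanog (3.01 ± 0.146 to 34.5 ± 8.18 FPKM, log2 3.12 ± 0.12) was higher in the Nanog-null iPSC. Pou5f1 (7139 ± 232 to 566 ± 46.2 FPKM, log2 -3.66 ± 0.13), Klf4 (2806 ± 366 to 23.2 ± 3.02 FPKM, log2 -6.86 ± 0.09) and Myc (1372 ± 190.3 to 8.84 ± 1.71 FPKM, log2 -7.13 ± 0.20) were lower, with the same limit on retroviral copies as above. Sox2 was 40.4 ± 1.54 against 40.1 ± 16.2 FPKM (log2 change 0.07 ± 0.17, limma adjusted p = 0.73). It became lower without WT piPSC 1 (log2 change -0.34, limma adjusted p = 0.027). Without WT piPSC 2 it became higher (log2 change 0.48, limma adjusted p = 0.0046). The largest rises were those of the fatty acid carrier gene Fabp3 (0.856 ± 0.151 to 1143 ± 75.1 FPKM, log2 9.27 ± 0.14), the imprinted RNA H19 (3.97 ± 1.21 to 2019 ± 174 FPKM, log2 8.69 ± 0.17) and Krt18 (0.427 ± 0.0112 to 535 ± 220.4 FPKM, log2 8.46 ± 0.19). The amino acid transporter gene Slc38a4 (0.460 ± 0.0876 to 461 ± 136 FPKM, log2 8.26 ± 0.15) and the serum amyloid gene Saa3 (0.935 ± 0.0152 to 688 ± 439 FPKM, log2 8.22 ± 0.22) came next. Besides Myc, Slc38a5 (1941 ± 14.8 to 0.144 ± 0.0386 FPKM, log2 -10.73 ± 0.41) and Nccrp1 (471 ± 105 to 0.224 ± 0.0834 FPKM, log2 -8.57 ± 0.20) had the largest falls. The transcriptional co-activator gene Eya2 (280.5 ± 4.34 to 0.206 ± 0.108 FPKM, log2 -7.87 ± 0.21) and Lgals7 (336 ± 38.3 to 1.12 ± 0.230 FPKM, log2 -7.31 ± 0.23) were next.

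General pluripotency genes were higher in Nanog-null iPSC than in piPSC, as 17 of 22 rose and 4 fell (17 and 4 adjusted over the list alone, camera adjusted p = 0.0002, adjusted p = 0.059 with an estimated correlation). Among them were Dppa5a (log2 6.93 ± 0.21), the zinc finger genes Zfp42 (log2 5.91 ± 0.30) and Sall4 (log2 4.75 ± 0.19), and Dnmt3l (log2 4.77 ± 0.37). Naive genes Dppa3 (log2 5.34 ± 0.35), Tbx3 (log2 5.31 ± 0.21) and Klf2 (log2 5.03 ± 0.14) rose, and in their list 10 of 17 rose and 3 fell (10 and 3 adjusted over the list alone, camera adjusted p = 0.046, adjusted p = 0.33 with an estimated correlation). Germline genes such as Tex19.1 (log2 4.35 ± 0.12) and Taf7l (log2 3.86 ± 0.11) were higher, and 13 of 15 rose and 1 fell (13 and 1 adjusted over the list alone, camera adjusted p = 0.00017). Of 2-cell stage genes, 9 of 9 rose and 0 fell (9 and 0 adjusted over the list alone, camera adjusted p = 0.0044, adjusted p = 0.41 with an estimated correlation). Zscan4f (log2 4.96 ± 0.47) and Zscan4d (log2 4.75 ± 0.53), whose copies share reads, were examples. Primitive endoderm genes such as Col4a1 (log2 6.10 ± 0.18) and Lama1 (log2 5.23 ± 0.24) were higher too. In this list 17 of 19 rose and 1 fell (17 and 1 adjusted over the list alone, camera adjusted p = 4.8e-07). For trophoblast genes, such as Krt7 (log2 6.03 ± 0.26) and Gata2 (log2 4.41 ± 0.11), 10 of 10 rose and 0 fell (10 and 0 adjusted over the list alone, camera adjusted p = 8.7e-05). Imprinted genes such as Igf2 (log2 7.02 ± 0.20) were higher, as 15 of 20 rose and 2 fell (15 and 2 adjusted over the list alone, camera adjusted p = 0.00032). Fibroblast genes such as Col1a1 (log2 7.07 ± 0.09) and Col3a1 (log2 6.84 ± 0.17) were higher, as 20 of 25 rose and 4 fell (21 and 4 adjusted over the list alone, camera adjusted p = 8.8e-06, adjusted p = 0.064 with an estimated correlation). Epithelial genes such as Krt8 (log2 7.47 ± 0.13) were higher as well, and 13 of 16 rose and 0 fell (14 and 1 adjusted over the list alone, camera adjusted p = 6.5e-05, adjusted p = 0.3 with an estimated correlation). Of the Wnt response genes, 11 of 12 rose and 1 fell (11 and 1 adjusted over the list alone, camera adjusted p = 0.00065, adjusted p = 0.3 with an estimated correlation). The feedback gene Axin2 (log2 4.16 ± 0.17) was higher and the cyclin gene Ccnd1 (log2 -3.73 ± 0.18) lower. The ERK response genes Dusp4 (log2 -4.28 ± 0.14) and Spry4 (log2 -3.05 ± 0.10) fell. Limma called 10787 genes, 5584 higher and 5203 lower. The count was 6939 without the batch term and 12415 within AC.

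The clones G2 and G5 were compared with each other. Fibroblast genes were higher in G2, as 13 of 25 rose and 0 fell (18 and 0 adjusted over the list alone, camera adjusted p = 2e-22). They included Col3a1 (73.7 ± 4.61 to 243 ± 4.2 FPKM, log2 1.71 ± 0.19) and Col1a1 (110.2 ± 4.77 to 291 ± 18.3 FPKM, log2 1.39 ± 0.11). Col5a1 (27.1 ± 0.617 to 68.4 ± 0.869 FPKM, log2 1.30 ± 0.18) and Dcn (57.4 ± 2.04 to 173 ± 16.6 FPKM, log2 1.57 ± 0.41) were others. The E3 ligase gene Rlim (1.5 ± 0.00131 to 33.6 ± 0.0926 FPKM, log2 3.79 ± 0.11) and the lectin gene Reg3g (0.452 ± 0.214 to 13.4 ± 0.929 FPKM, log2 3.32 ± 0.13) rose most. The imprinted zinc finger gene Plagl1 (3.98 ± 0.0357 to 33.8 ± 0.0540 FPKM, log2 2.81 ± 0.27) and the serpin gene Serpina3n (9.0 ± 0.896 to 55.0 ± 1.65 FPKM, log2 2.49 ± 0.14) followed. AC154650.1 (556 ± 8.42 FPKM in G2, listed at 0 in G5) met the same rule but rested on 1 or 2 fragments a sample and was not called by edgeR (adjusted p = 0.37). Lower in G2 were the GTP-binding protein gene Gtpbp1 (84.4 ± 6.42 to 9.85 ± 0.168 FPKM, log2 -2.97 ± 0.09) and the phospholipase receptor gene Pla2r1 (6.12 ± 0.142 to 0.650 ± 0.0396 FPKM, log2 -2.11 ± 0.18). The mannosyltransferase gene Dpm1 (67.3 ± 3.91 to 23.8 ± 5.53 FPKM, log2 -1.48 ± 0.20) was lower too. So were the interferon response genes Isg15 (22.8 ± 1.43 to 8.49 ± 1.18 FPKM, log2 -1.33 ± 0.26) and Oasl1 (6.09 ± 1.14 to 1.80 ± 0.0261 FPKM, log2 -1.33 ± 0.24). Nanog (41.5 ± 2.11 to 27.5 ± 0.418 FPKM, log2 -0.58 ± 0.14) was lower in G2. Pou5f1, Sox2, Klf4 and Myc did not pass (limma adjusted p = 0.64, 0.92, 0.14 and 0.52). Klf4 passed within AC (log2 change 0.31, limma adjusted p = 0.04) and with G2 and G5 alone in the fit (adjusted p = 0.033).

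Germline genes, including Taf7l (log2 -1.09 ± 0.12) and Tex19.1 (log2 -0.95 ± 0.14), were lower in G2, and 0 of 15 rose and 4 fell (0 and 7 adjusted over the list alone, camera adjusted p = 0.00014). General pluripotency genes were lower too, as 0 of 22 rose and 4 fell (0 and 4 adjusted over the list alone, camera adjusted p = 0.049, adjusted p = 0.43 with an estimated correlation). They included Lefty2 (log2 -1.02 ± 0.24), Tdgf1 (log2 -0.76 ± 0.16), Lefty1 (log2 -0.74 ± 0.12) and Fbxo15 (log2 -0.73 ± 0.16). Wnt response genes were higher, as 3 of 12 rose and 0 fell (4 and 0 adjusted over the list alone, camera adjusted p = 1.8e-05, adjusted p = 0.32 with an estimated correlation). They included Sp5 (log2 1.12 ± 0.27) and the stem cell receptor gene Lgr5 (log2 0.98 ± 0.10). The keratin genes Krt8 (log2 -1.07 ± 0.15) and Krt18 (log2 -1.07 ± 0.22) were lower. Limma called 820 genes, 480 higher and 340 lower in G2, and 154 of them changed at least 2-fold. Leaving out the genes called higher in MEF, 282 of 9362 genes were called and 34.8% of them were higher. The count was 330 without G2 1, 232 without G2 2, 267 without G5 1 and 306 without G5 2. Of the 25 named genes called, Dcn, Fbxo15, Isg15, Krt18, Lefty2, Nanog, Oasl1, Sp5 and Tdgf1 lost the call in at least 1 of these fits. There were 8 lost without G2 1 or G5 2, and 9 without G2 2 or G5 1. In AC alone 2776 genes were called. With no batch term 126 were, and 16 of the 25 named calls were lost.

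Sex-linked genes were read as values. Xist, the RNA of the inactive X, was 317 ± 4.47 FPKM in WT piPSC and 39.7 ± 0.285 in WT MEF. In WT ESC it was 3.22 ± 0.183 in AC and 9.41 ± 4.35 in JI samples, and in WT iPSC 3.15 in the AC sample and 9.03 ± 2.46 in JI. It was 11.7 ± 0.464 in Nanog-null ESC, 12.6 ± 0.253 in G2 and 6.67 ± 0.121 in G5. The Y-linked gene Ddx3y was 22.8 ± 0.254 FPKM in Nanog-null ESC, 21.5 ± 0.0958 in MEF and 3.94 ± 0.377 in AC samples of WT ESC. It was 2.00 ± 0.105 in G2, 1.13 ± 0.0352 in G5 and 0.0166 ± 0.00449 in piPSC. WT iPSC had 0.873 in the AC sample and 2.72 and 2.84 in JI, and JI samples of WT ESC had 0.820 and 1.31. Eif2s3y was 24.7 ± 0.458 in Nanog-null ESC, 4.12 ± 0.117 in G2, 2.27 ± 0.451 in G5 and 0.0420 ± 0.0594 in piPSC. It was 10.5 and 10.9 in AC and 2.06 and 2.63 in JI samples of WT ESC. WT iPSC had 1.93 in the AC sample and 15.9 and 14.3 in JI, and WT MEF had 18.3 and 18.9.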

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

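The tests of feeder RNA and of a difference common to both batches were chosen only after the results were seen.

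Primitive endoderm and fibroblast genes rose together in Nanog-null ESC and in the mean of the Nanog-null iPSC clones, lines that the protocols place on feeder cells. If RNA of those feeders were the only source of the fibroblast genes, the excess over WT ESC in G2 and G5 would differ by 1 common factor, but 10 of 22 members lay over 2 SE from the median factor of 2.54 (1.07 for Cd44 to 4.31 for Col3a1). The same source does not account for the primitive endoderm genes, since 14 of 18 called members were above their level in pure WT MEF in Nanog-null ESC, such as Lama1 (86.4 against 0.778 FPKM) and, chosen after their values were seen, Gata4 (18.8 against 0.186) and Sox17 (16.1, listed at 0 in MEF). A feeder share in part, feeders in another state than these passage 2 MEF, and, as a hypothesis, a subset of Nanog-null cells with endoderm and mesenchymal expression remain open, and none of these was tested. Of the members tested, 21 of 25 fibroblast and 8 of 19 primitive endoderm genes had an FPKM of at least 1 in AC samples of WT ESC, no other fixed list held any of them, and the median of 89 MEF-abundant genes was 10.0% of the MEF level in G2, 7.08% in G5, 10.1% in Nanog-null ESC and 1.94% in AC samples of WT ESC.

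WT iPSC and WT ESC differed in 156 genes by limma, a count that was 28, 11, 2675 and 1809 without WT ESC 1, 2, 3 and 4 and 84 without WT iPSC 2. As many genes were called in 4 of 34 splits of their 7 samples, the real one included. Chance therefore cannot be excluded where samples are exchanged freely. The highest other count was 2627, with WT ESC 1, 2 and 4 on one side. That split differs from the real one only in placing WT ESC 3 with the WT iPSC, and it is not a split within batch. Over the genes tested, WT ESC 3 correlated with WT iPSC 2 and 3 of its batch at 0.9905 and 0.993, and with WT ESC 4 at 0.983. The split by batch could not be fitted. Exchanged only within batch, the samples make 18 splits, too few for a share under 0.05, with 141 genes as the highest other count. A difference common to iPSC of both batches as its main part would correlate across genes between AC and JI, and r was -0.0105. The AC side rests on 1 WT iPSC sample, and within JI limma called 0 genes. Spread between samples also lowers r, so this value cannot exclude a modest common difference. Open are a common difference in part of the genes and the clones and passages, which were untested.

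For Nanog-null iPSC against WT iPSC, with both clones as 1 group, limma called 8546 genes. Of 35 splits of the 7 samples, 1 (the real one) called as many, and the highest other called 2473. That share, 0.0286, is the smallest that 35 splits allow. Free exchange treats samples of different batches and replicates of 1 clone as alike, so these splits cannot exclude chance. All Nanog-null iPSC are of AC and 2 of the 3 WT iPSC of JI. Exchanged only within batch they make 5 splits, too few for a share under 0.05.

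The iPSC minus ESC difference itself differed between Nanog-null and WT lines, by the interaction term, for 1686 genes. Among them, with log2 values, were Nanog (-0.56), Myc (-1.26), Ttr (-1.65), Col4a1 (-1.41), Col4a2 (-1.25), Dnmt3l (-3.07), Lin28a (-2.19) and Krt18 (2.24). That count was 593 and 641 without Nanog-null ESC 1 and 2, 1064, 1096 and 1039 without G2 1, G2 2 and G5 1, and 3151 and 3290 without WT ESC 3 and 4. Without the batch term it was 158, and none of these 8 genes was called by limma.

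Peg10, an imprinted gene of the fixed list that was left out of the tests for a failed status, had 595 ± 32.5 FPKM in Nanog-null ESC, 399 ± 5.40 in G2 and 448 ± 54.3 in G5. The status stood in all 6 Nanog-null samples and in none of the other 11, so these high values are themselves failed quantifications. It had 5.24 ± 1.56 in WT ESC, 4.29 ± 0.582 in WT iPSC, 0.583 ± 0.165 in WT piPSC and 9.71 ± 0.163 in WT MEF.

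In WT ESC, the group with 4 samples, 1 sample stood far from the other 3 for 7 of 145 named genes. These were Fosl1 (0.280 FPKM), Dppa3 (214) and Meg3 (94.3) in WT ESC 3, Vax2 (4.34) and Pla2r1 (0.838) in WT ESC 4, Acss1 (6.27) in WT ESC 1 and Taf7l (3.25) in WT ESC 2. Chance sets about 1 in 20 groups of 4 exchangeable samples apart, but 2 of these are of AC and 2 of JI, and that rate leaves the batches out.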

How the results depend on the processing

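The edgeR fits, the fits of batch JI alone and those without genes called higher in MEF were chosen only after the result was seen. Of 259 named results, 239 kept their sign and their side of the threshold with a pseudocount of 0.1, 252 without a filter, 252 with quantile normalization, 181 without the batch term and 255 by edgeR. Of the 242 that were called, 20, 7, 5, 73 and 4 lost the call in these fits. Over all settings the sign changed 3 times with a call in the main fit or the alternative, and 22 times without one. Of the 3, Krt18 in WT iPSC against WT ESC changed sign without the batch term (0.11, limma adjusted p = 0.99). Klf4 in Nanog-null iPSC against WT iPSC did so without it too (0.33, limma adjusted p = 0.70). Sox2 in Nanog-null iPSC against WT piPSC did so without WT piPSC 1 (-0.34 by limma). Over the samples left out in turn, that Sox2 change ranged from -0.34 to 0.48. For each count below the cause was not tested, except that fewer genes enter with a higher filter and fewer samples in the fits of part of the data.

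Counts of called genes are given in the order MEF against ESC, WT iPSC against ESC, piPSC against WT iPSC, Nanog-null ESC against WT ESC, Nanog-null iPSC against WT iPSC, against Nanog-null ESC and against piPSC, G2 against G5 and the interaction. They are given only where they moved over 1.5 times. With a mean FPKM of at least 5 they were 8040, 6276, 5407, 5833, 884, 6769, 438 and 1026, all but WT iPSC against ESC. With a fold of at least 2 they were 8047, 5, 4845, 2391, 2726, 247, 4851, 154 and 448. A pseudocount of 0.1 gave 64 for WT iPSC against ESC and 449 for G2 against G5. Without the batch term WT iPSC against ESC had 0 limma calls (910 at an unadjusted p under 0.05, 0 by edgeR), and Nanog-null ESC against WT ESC 4888. Nanog-null iPSC against Nanog-null ESC had 274 and against piPSC 6939, G2 against G5 126, the interaction 158 and genes called alike in both Nanog-null comparisons 4179 (6506 with it). In AC alone the counts were 6191 for WT iPSC against ESC, 4545 for Nanog-null iPSC against Nanog-null ESC, 2776 for G2 against G5 and 6674 for the interaction. With only the groups compared in the limma fit, WT iPSC against ESC had 0 (1318 at an unadjusted p under 0.05, 8 by edgeR). Then Nanog-null iPSC against Nanog-null ESC had 5206 and G2 against G5 2168. In JI alone WT iPSC against ESC had 0 limma calls (945 at an unadjusted p under 0.05, 3 by edgeR). By edgeR there were 1319 for WT iPSC against ESC and 2549 for the interaction. The edgeR median change of all genes for piPSC against WT iPSC was -0.17, against -0.06 in limma. Without genes higher in MEF the counts were 4898, 5332, 970, 6476 and 282 for the Nanog-null ESC, the 3 Nanog-null iPSC and the clone comparisons and 1063 for the interaction. With an estimated correlation 24 lists were called.

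Replicate numbers did not pair the samples: over 15 pairs of same-numbered samples of different groups the correlation of deviations was -0.056 to 0.11, with 1 above 0.1. With the numbers as a block the limma counts were 1017 for WT iPSC against ESC and 2878 for the interaction, and camera called 66 lists. The block brought Pou5f1 past the limma threshold in Nanog-null ESC against WT ESC (-0.35, adjusted p = 0.001) and in Nanog-null iPSC against WT iPSC (-0.21, adjusted p = 0.018). Leaving out each sample in turn gave 11527 to 12462 genes for MEF against ESC, 11 to 2675, 8653 to 9689, 6059 to 9332, 7974 to 8523, 537 to 1171, 9505 to 10265, 232 to 330 and 593 to 3290 in the order above. The difference in position was -0.351 to -0.266, and its exact p cannot then pass. It was -0.191 with AC and -0.338 with JI samples of WT ESC as the ESC end. The lone sample left in a group of 2 is assumed to vary like the other groups. Genes with an FPKM of 0.5 to 2 rested on a median of 15 fragments in the shallowest library, WT ESC 4 (7.80 M fragments), and of 106 in the deepest, Nanog-null ESC 2 (43.5 M). How calls depend on depth was not tested.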

Other observations

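The test of Hprt was chosen only after the result was seen, and so were the genes in the next paragraphs unless a fixed list holds them.

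WT cells of the batches differed more than WT iPSC and WT ESC did. In the fit of all samples, limma's batch term called 11081 genes, 5816 higher and 5265 lower in JI than in AC. Of 17 naive and LIF response genes, 14 were lower and 3 higher in JI (camera adjusted p = 0.0014, adjusted p = 0.53 with an estimated correlation). Over WT ESC and WT iPSC samples (SD, n = 3 in AC and 4 in JI), Klf2 was 102 ± 5.73 FPKM in AC and 18.4 ± 4.00 in JI. Klf4 was 62.6 ± 4.35 and 11.5 ± 2.04, and Tfcp2l1 81.4 ± 10.7 and 8.71 ± 2.23. Epithelial genes were higher in JI (13 of 16, 2 lower, camera adjusted p = 0.0014, adjusted p = 0.59 with an estimated correlation). Krt18 was 5.2 ± 2.85 in AC and 328 ± 97.9 in JI. Glycolysis and hypoxia genes were higher in JI too (10 of 12, 1 lower, same p values), and the 9 genes of the 2-cell stage were all lower (same p values). The methyltransferase cofactor gene Dnmt3l had 8.10 ± 9.06 FPKM in AC and 236 ± 29.6 in JI. The immediate early gene Fos had 0.498 ± 0.195 and 11 ± 2.19, and the smooth muscle gene Tagln 8.45 ± 1.53 and 632 ± 92.5. Strain, batch and culture cannot be told apart here.

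Esrrb, an orphan nuclear receptor gene of the naive list that was left out of the tests for its status, was 166 ± 2.34 FPKM in AC and 52.5 ± 3.11 in JI samples of WT ESC. It was 64.4 ± 2.86 in Nanog-null ESC, 80.6 ± 4.17 in G2, 69.3 ± 6.71 in G5, 0.523 ± 0.0170 in WT piPSC and 0.0470 ± 0.0660 in WT MEF.

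The X-linked E3 ligase gene Rlim was 1.5 ± 0.00131 FPKM in clone G5 (n = 2) and 33.6 ± 0.0926 in G2, with group and batch means of 13.7 to 33.8 elsewhere. Gtpbp1 was 84.4 ± 6.42 in G5 and 9.85 ± 0.168 in G2, with means of up to 22.1 elsewhere. The AC sample of WT iPSC had 137 FPKM of Zscan4d, a 2-cell stage gene whose copies share reads, and 46.1 of the chitinase gene Chit1, against 15.7 ± 3.40 and 4.31 ± 0.603 in AC samples of WT ESC. The gene models Gm9000 and Gm8730 were 6.49 and 7.82 FPKM in that iPSC sample, against 375 ± 11.8 and 394 ± 2.46 in AC samples of WT ESC. Means of the Nanog-null groups for these 2 gene models were 387 to 428, and WT piPSC had 1.66 ± 0.284 and 1.94 ± 0.109. JI means of WT ESC and WT iPSC were 16.4 to 89.9. The source of these differences was not tested.

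Hprt was 5.57 to 12.6 FPKM in the 6 Nanog-null samples and 69.4 to 250 in the other 11. A hypothesis that low Nanog RNA is enough to lower Hprt is argued against by WT piPSC, which had 179 ± 21.4 FPKM of Hprt (SD, n = 2) with a Nanog FPKM of 3.01, below all Nanog-null samples. A trait of the parental Nanog-null line apart from Nanog may be the source of the low Hprt; it remains untested, since the protocols derive the Nanog-null iPSC from a parental Nanog-null ESC line and no label says whether the sequenced ESC are that line.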
